A study of Homo sapiens with 41 samples.

How the data were processed

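Synaptosomes from 41 postmortem human brains, 27 with Alzheimer's disease (AD) and 14 controls, were profiled by paired-end sequencing of stranded libraries of polyadenylated RNA, per the labels' protocols. The brain region is not given in the sources used here. A small-RNA data set that the design text mentions was not analysed here. Groups were taken from the sample titles, and each brain counted as 1 replicate.

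The authors deposited counts of read pairs per gene, made by featureCounts 2.0.1 in 1 run over all libraries with exons summed per gene, paired ends, strand setting 2 (reverse stranded) and the Ensembl release 101 annotation, per the file headers. HISAT2, DESeq2 and the genome build GRCh38.p13 are named in the submitters' processing notes, with no versions for these tools and no statement of which step used DESeq2. Because strand was used in counting, antisense partners were kept apart, whereas near-identical copies could share or lose reads. HSPA1A and HSPA1B, C4A, MT1H and MTRNR2L8 are such genes and their values are uncertain. The authors also deposited FPKM per gene in a table for each library, per the column names in the file headers, and these served only in an alternative. The deposited coverage and TPM columns were treated as a score with no fixed scale and entered no test, since the TPM columns summed to between 1356849 and 2319257. Genes of different length keep different numbers of fragments when RNA is degraded or a library holds few molecules, and a length trend between groups can then move whole gene lists; the closing section tests this.

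The count table had 60673 lines, of which 3 held 1 gene broken over several lines. That gene was left out and 60670 were read, all of which had a name in the per-library tables. Gene positions are those of the count table in GRCh38. Gene types came from GENCODE 29, in which 58452 genes matched, and GC content was that of each gene's longest GENCODE 29 transcript. Genes without a GC value took the median in the length and GC offset. Exonic length was that of the count table, over all annotated exons of a gene. Because the donors are people, 524 genes (Y-linked genes, XIST and TSIX) were left out before any step, leaving 60146.

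Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on group (minimum count 10), scaled by TMM, fitted with glmQLFit (robust) with disease as the 1 factor and no covariate, and tested with glmQLFTest. Tests were two-sided, with Benjamini-Hochberg adjustment over the 12066 genes kept and a threshold of 0.05. CPM values are TMM-scaled, and the standard error of a log2 fold change was derived from the fit. Library totals ran from 1330960 to 17404023 counts in AD and from 2803476 to 15183167 in control. Outside the mitochondrial genes the totals were 330713 to 12311459 and 917587 to 13169194. The common biological coefficient of variation was 0.574. On simulated counts with the real means and library sizes (27 against 14 libraries, 12066 genes) the test recovered 4.48% of 67 genes changed 1.5-fold, 47.8% of 67 changed 2-fold and 100% of 66 changed 4-fold. Of its calls, 2.75% were unchanged genes. The simulation held no correlation between genes, no depth classes and no length trend, so this rate need not hold in the real libraries.

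Before the data were examined 33 gene lists were fixed, 21 of functions, 11 of cell type markers and 1 of nuclear retained noncoding RNA as a sign of RNA quality, with a panel of 13 genes. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided), adjusted over the 33 lists. Camera weighs the mean of a list, so its direction can differ from that of the median. On simulated data a shifted list had camera p = 1.58e-23 and an unchanged list p = 0.732. Genes were simulated independently, so these values do not show how often camera calls a list of correlated genes. List scores were the mean log2 CPM of the members in each library. Differences in mean, in mean absolute deviation from the group median and in 5 measures of library composition were tested by two-sided permutation with 100000 resamples (smallest p 1e-05). Further, 4 pairs of scores were correlated within each group, 8 correlations in all. Where a class held fewer than 10 libraries of a group the permutations were enumerated exactly. Tests per library used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

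The genes named were chosen by a rule fixed in advance. It took the 8 genes with the smallest p in each direction among those past the threshold with a gene symbol and a mean of at least 1 CPM. It added up to 4 members with the smallest p for each list described and the panel whatever its result. It also took the 2 largest log2 fold changes in each direction among genes past the threshold with a mean of at least 1 CPM. Some genes that this rule takes are not reported here.

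Depth classes were set after the data were seen, at the largest relative gap between library totals, and values within classes are given beside the pooled ones. No pair of libraries matched within sampling noise, the smallest chi-square per degree of freedom over 820 pairs being 5.24. Alternatives planned in advance were size factors of DESeq2, upper-quartile factors, no filter, a filter of 1 CPM in 14 libraries, the Wald test of DESeq2 1.42.0, limma voom with quality weights, and a rank sum permutation test. Further planned ones were surrogate variables from sva 3.50.0, log2 library size as covariate, the replicate number as a block, mitochondrial genes left out, and counts thinned to the smallest library. The rest were each library left out in turn, a log2 fold change of at least 1, limma on log2(FPKM + 1), and for lists an estimated correlation and fry. Added after the data were seen were depth class as a covariate, each class alone, the level of RN7SL1 or the percent of mitochondrial counts as a covariate, libraries without 5.8S ribosomal RNA (under 1 CPM) left out. A further one was an offset for exonic length and GC (splines with 5 degrees of freedom per library) with and without depth class. Matched lists were drawn 10000 times from the 50 genes nearest to each member in exonic length, GC and level, and 100 splits of the libraries into 27 and 14 were fitted anew. Matched members were drawn independently, so the spread of matched lists leaves out the correlation between members.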

Results

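Polyadenylated RNA was measured in synaptosomes, the resealed nerve endings and attached postsynaptic membranes that are recovered when brain tissue is fractionated, from 41 postmortem human brains. There were 27 brains with Alzheimer's disease (AD) and 14 control brains, with 1 stranded library each, and the values were counts of read pairs in the exons of each gene. The comparison asked which transcripts of this fraction differed between AD and control. Library totals ran from 1330960 to 17404023 counts in AD (median 3409442) and from 2803476 to 15183167 in control (median 6488550). A gap between 5620323 and 7687200 counts separated 30 shallow libraries (23 AD, 7 control) from 11 deep libraries (4 AD, 7 control). RN7SL1 ran from 8.57 to 22.2 CPM in deep AD and from 835 to 20322 CPM in shallow AD libraries. In control it ran from 18.7 to 1791 CPM in deep and from 1168 to 8269 CPM in shallow libraries. The 4 AD and 3 control libraries without 5.8S ribosomal RNA (under 1 CPM) were all deep. The classes thus differed in RNA content as well as depth, and no label gives a batch. The depth classes were not shared evenly between AD and control (Fisher's exact test, two-sided p = 0.0262). Values within these classes are therefore given for each list that passed over all libraries or within a class. The adjusted p of a list within a class is from camera with the preset correlation unless a permutation test is named. The estimated correlation was not applied within classes.

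Transcripts of the mitochondrial genome made up 60.7% ± 17.7 (SD, n = 27) of the counts in AD and 48.9% ± 21.0 (n = 14) in control. The difference did not pass a two-sided permutation test (p = 0.0653, adjusted p = 0.109). Within depth classes this difference was 6.29 percentage points (permutation p = 0.353). The number of genes detected was 17122 ± 2208 in AD and 18724 ± 2099 in control (p = 0.0314, adjusted p = 0.109). Haemoglobin transcripts, a measure of residual blood, took 0.00649% ± 0.00952 of the counts in AD and 0.00853% ± 0.00666 in control (adjusted p = 0.503). The 10 most abundant genes took 57.6% ± 16.5 in AD and 46.7% ± 18.9 in control (adjusted p = 0.109), and the adjusted p for total counts was 0.118. Of the 5 measures of library composition, 0 passed the permutation test after adjustment, and 1 had an unadjusted p under 0.05.

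AD synaptosomes held more RNA for PRELP, a leucine-rich proteoglycan of the extracellular matrix, and for the chromatin and transcription factors KDM6B, BCL6 and CIC. PRELP (ENSG00000188783, a protein-coding gene on chromosome 1 from 203475806 to 203491352 in GRCh38) stood at 27.6 ± 7.08 CPM (counts scaled to the library size after TMM correction; mean ± SD, n = 27) in AD and 11.6 ± 7.69 CPM (n = 14) in control. Its log2 fold change was 1.26 ± 0.20 (SE), or 2.40-fold (adjusted p = 0.000803), and all 27 AD libraries lay above the control median. KDM6B, a histone demethylase, was 2.60-fold higher (17.8 ± 9.91 against 6.73 ± 2.41 CPM, adjusted p = 0.0013, 27 of 27 AD libraries above the control median). The transcriptional repressors BCL6 (log2 fold change 0.98 ± 0.17) and CIC (0.96 ± 0.17) and the corepressor ATN1 (0.98 ± 0.19) were each close to a doubling, with 26, 26 and 25 AD libraries above the control median. MDGA1, a membrane-anchored protein that binds neuroligins, was 2.25-fold higher, PSD2, an exchange factor for ARF GTPases, 2.41-fold higher, and the tankyrase-binding protein TNKS1BP1 1.71-fold higher. The largest rises among genes past the threshold with a mean of at least 1 CPM were those of A2ML1, a protease inhibitor (1.96 ± 0.41, adjusted p = 0.00397), and MTRNR2L8 (1.98 ± 0.59, adjusted p = 0.0364). MTRNR2L8 is a near copy of mitochondrial ribosomal RNA, so its counts are uncertain, and its change was -0.49 in the deep libraries alone. Its call ended in 8 single omissions (adjusted p up to 0.0715).

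Lower in AD were CMTM5, TUBA1A, RBM3 and a set of genes that includes MAG and PLLP of myelin. CMTM5 (ENSG00000166091, protein-coding, chromosome 14 from 23376773 to 23379772) stood at 5.78 ± 3.27 CPM in AD and 25.9 ± 37.6 CPM in control, 4.45-fold lower (log2 fold change -2.15 ± 0.35, adjusted p = 0.000803). All 27 AD libraries lay below its control median. TUBA1A, an alpha-tubulin, was 3.30-fold lower (168 ± 93.2 against 556 ± 591 CPM, adjusted p = 0.000803), and the cold-inducible RNA-binding protein RBM3 was 4.25-fold lower (-2.09 ± 0.35, adjusted p = 0.000803). TF, which encodes the iron carrier transferrin, was 4.99-fold lower (chromosome 3 from 133746040 to 133796641, 51.5 ± 37.9 against 258 ± 428 CPM, adjusted p = 0.0013). MAG, the myelin-associated glycoprotein (ENSG00000105695, chromosome 19 from 35292125 to 35313807), was 5.14-fold lower, with medians of 23.5 CPM in AD and 56.2 CPM in control (adjusted p = 0.00214, 23 of 27 AD libraries below the control median). PLLP, a myelin proteolipid (4.02-fold lower), CARNS1, which makes carnosine (4.86-fold lower), and TMEM125 (5.37-fold lower) fell as well. The largest fall among genes past the threshold with a mean of at least 1 CPM was that of HAPLN2, a hyaluronan-linking protein of nodes of Ranvier (-2.45 ± 0.48, adjusted p = 0.00214, 18 of 27 AD libraries below the control median). Without control replicate 7 the HAPLN2 change was -1.19 and no longer passed (adjusted p = 0.0679; 0.00113 to 0.0679 over all single omissions). Without it the falls of CMTM5, TF, MAG, PLLP, CARNS1 and TMEM125 were 2.86-fold, 3.00-fold, 2.93-fold, 2.52-fold, 2.62-fold and 3.39-fold, and each still passed (adjusted p up to 0.0232).

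By the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment, 876 of 12066 genes tested passed an adjusted p of 0.05, 357 higher and 519 lower in AD (59.2% lower), and 3122 had an unadjusted p under 0.05. Of the genes called, 859 were protein-coding. In the 30 shallow libraries alone 5 genes passed higher and 0 lower (1529 at an unadjusted p under 0.05), and in the 11 deep libraries 1 higher and 0 lower (1643). PRELP rose in the shallow libraries too (1.41 ± 0.20, adjusted p = 0.00038), whereas CMTM5 (-1.31), TUBA1A (-1.02), TF (-1.66) and MAG (-1.63) kept their sign there without passing, at adjusted p = 0.122, 0.117, 0.122 and 0.156. Over all alternatives apart from single omissions the adjusted p of PRELP ran from 2.09e-07 to 0.475, of CMTM5 from 4.28e-06 to 0.394, of TUBA1A from 3.07e-06 to 0.421, of TF from 1.31e-05 to 0.394 and of MAG from 4.81e-05 to 0.394. With depth class as a term 133 genes passed higher and 90 lower, and with that term and an offset for exonic length and GC 19 and 11. Under both together PRELP, CMTM5, TUBA1A and MAG still passed, and KDM6B (adjusted p = 0.148), CIC (0.171), ATN1 (0.22), TF (0.112) and PLLP (0.12) did not. The change followed exonic length summed per gene. Of the 2414 shortest genes (65 to 3083 bases) 14 were higher and 190 lower (median log2 fold change -0.40). Of the 2413 longest (9026 to 122609 bases) 152 were higher and 40 lower (median 0.20). Calls also split by GC content, with 12 higher and 156 lower among the 2410 genes of lowest GC. Among the 2410 of highest GC 140 were higher and 42 lower, though the medians were close (-0.06 and -0.03). Spearman rho of the log2 fold change with exonic length was 0.40 over all libraries and 0.09 with depth class as a term. This rho was 0.21 in the shallow and -0.11 in the deep libraries. On the deposited FPKM values limma called 0 genes higher and 890 lower (5584 at an unadjusted p under 0.05) around a median of all genes of -0.34, and CIC (-0.23) and ATN1 (-0.18) were negative on that scale but above its median, by 0.10 and 0.16. The FPKM values were not rescaled between libraries, whose FPKM sums ran from 285020 to 1.29e+06. A difference in scale can move all genes the same way, so this split cannot be read as changes of single genes. Without control replicate 7 the edgeR counts were 208 higher and 229 lower.

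**Figure D1:**
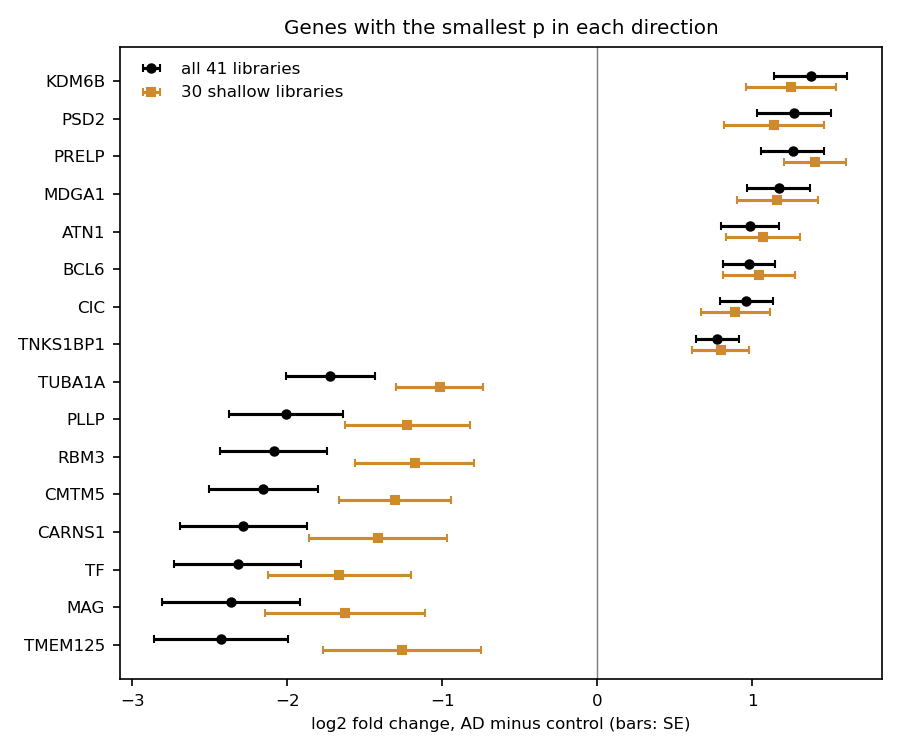
Log2 fold change, AD minus control, of the 8 genes with the smallest p in each direction (points, bars are SE), fitted over all 41 libraries (black) and over the 30 shallow libraries (orange). Each of the 16 genes kept its sign in the shallow libraries, where the genes lower in AD lay nearer 0, such as TUBA1A at -1.02 against -1.72, and CIC and ATN1 were negative on the FPKM scale, though above its median of all genes.

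Among the cell type markers, those of mature oligodendrocytes, the myelin-forming cells, had the lowest median log2 fold change in AD synaptosomes. The list passed camera, a test of a list against all other genes (adjusted p = 3.29e-05), but not with an estimated correlation between its genes (adjusted p = 0.589 with an estimated correlation). Of 19 markers tested 13 fell and 0 rose, all 19 fitted changes were negative, and their median log2 fold change was -1.36. TF, PLLP and MAG led the list, followed by KLK6, a secreted serine protease (3.88-fold lower, adjusted p = 0.00575). Adjusted over the list alone, 16 markers passed. Its median was -1.16 in the shallow and -2.08 in the deep libraries, and it passed in both (adjusted p = 0.00971 and 3.03e-07). The call of KLK6 ended without control replicate 7 (-1.19, adjusted p = 0.0644; 0.00255 to 0.0644 over single omissions).

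Markers of oligodendrocyte precursors did not move as a list, with 1 of 10 tested markers lower and 0 higher, a median of -0.10 and a camera direction of up (adjusted p = 0.977). The lower marker was OLIG2, a lineage transcription factor (-0.98 ± 0.31, adjusted p = 0.0444). Its call ended in 20 single omissions, and without control replicate 7 the change was -0.42 (adjusted p = 0.339). Astrocyte markers were higher as a list (median 0.30, adjusted p = 0.00197, and adjusted p = 0.589 with an estimated correlation). Of 18 markers 2 rose, among them SOX9, a glial transcription factor (0.91 ± 0.28, adjusted p = 0.0401), and 0 fell, and 2 were higher adjusted over the list alone. SOX9 was negative in the deep libraries (-0.24), and its call ended in 15 single omissions (adjusted p up to 0.0688). The astrocyte list median was 0.22 in the shallow and -0.24 in the deep libraries (adjusted p = 0.00282 and 0.823). Of 18 microglial markers 0 passed either way by edgeR (median 0.09, camera direction down, adjusted p = 0.691), and P2RY12, a purinergic receptor, had a log2 fold change of -1.07 ± 0.38 (adjusted p = 0.0753). With depth class as a term 2 of these passed lower, P2RY12 (-1.50, adjusted p = 0.031; 0.00352 to 0.394 over all alternatives) and the fractalkine receptor CX3CR1 (-1.34, adjusted p = 0.0429; 0.0243 to 0.47). Excitatory neuron markers split, CUX2, an upper-layer transcription factor, rising (0.90 ± 0.29, adjusted p = 0.0445; -0.08 on the FPKM scale, 0.26 above its median of all genes) and NEUROD6 falling (-1.19 ± 0.39, adjusted p = 0.0494). Of these 12 markers 1 passed in each direction, also when adjusted over the list alone (list adjusted p = 0.386). The CUX2 call ended in 24 single omissions (adjusted p up to 0.072) and that of NEUROD6 in 29, its change being -0.81 without control replicate 9 (adjusted p = 0.177). Of 14 inhibitory neuron markers 1 fell, the neuropeptide gene SST (2.62-fold lower, adjusted p = 0.0378, 24 of 27 AD libraries below the control median). Of these 2 were lower adjusted over the list alone (median -0.42, list adjusted p = 0.131). The list passed in the shallow (median -0.41, adjusted p = 0.0153) but not in the deep libraries (-0.37, adjusted p = 0.631), with adjusted p from 0.0123 to 0.697 over all alternatives. The SST call ended in 6 single omissions (adjusted p up to 0.079).

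Nuclear genes for the respiratory chain, the proteasome and cytosolic ribosomes were lower in AD as lists in camera. None of these calls held with an estimated correlation (adjusted p = 0.515, 0.515 and 0.589 with an estimated correlation). Of 74 nuclear encoded oxidative phosphorylation genes 18 fell and 0 rose (52 lower adjusted over the list alone), with a median of -0.73 and all 74 fitted changes negative. They included NDUFB6 (-0.96 ± 0.22, adjusted p = 0.00681) and NDUFA5 (-0.85 ± 0.21, adjusted p = 0.0131) of complex I and ATP5PB of the ATP synthase (-0.76 ± 0.17, adjusted p = 0.00812). Of 30 proteasome subunits 10 fell and 0 rose (23 lower adjusted over the list alone, median -0.71). Among them were PSMB2 (-0.65 ± 0.15), PSMA5 (-0.93 ± 0.22) and PSMD6 (-0.84 ± 0.20), with 26, 25 and 26 of 27 AD libraries below the control median. All 74 cytosolic ribosomal protein genes had negative fitted changes (median -0.75), but 1 passed, RPL15 (-0.73 ± 0.18, adjusted p = 0.0115), over all genes as adjusted over the list alone.

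In camera the respiratory (adjusted p = 2.37e-20), proteasome (adjusted p = 3.21e-11) and ribosomal lists (adjusted p = 1.95e-14) passed. Their medians in the shallow libraries, where all of them passed, were -0.57, -0.45 and -0.38, and in the deep libraries, where none of these lists passed (adjusted p = 0.631, 0.0951 and 0.176), -0.16, -0.35 and -0.31. The 13 respiratory chain genes of the mitochondrial genome went the other way in camera (median 0.38, adjusted p = 0.0378, and adjusted p = 0.726 with an estimated correlation). By edgeR 0 of the 13 passed, over all genes or adjusted over the list alone, and their median was 0.94 in the shallow and -0.33 in the deep libraries (adjusted p = 0.0061 and 0.895). That list's call ended when any of 16 single libraries was left out, 8 of them AD, with adjusted p up to 0.113. Its median was 0.23, 0.21, 0.21 and 0.19 without AD replicate 6, 7, 23 or 25, and 0.97 without control replicate 3.

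Cholesterol synthesis, autophagy and glycolysis genes were lower as lists in camera as well (adjusted p = 0.00039, 0.00107 and 0.0465). None of these calls held with an estimated correlation (adjusted p = 0.515, 0.515 and 0.589 with an estimated correlation). Of 20 cholesterol synthesis genes 6 fell and 0 rose (11 lower adjusted over the list alone, median -0.65). IDI1, an isomerase of the isoprenoid steps, was 2.05-fold lower (adjusted p = 0.00222), and HMGCS1, which makes the substrate of the rate-limiting reductase, was 1.90-fold lower (adjusted p = 0.00473, 26 of 27 AD libraries below the control median). Of 36 lysosome and autophagy genes 4 fell and 0 rose (7 lower and 1 higher adjusted over the list alone, median -0.41), led by GABARAPL2, which conjugates to autophagosome membranes (1.90-fold lower, adjusted p = 0.00569). Glycolysis genes had a median of -0.31, with 0 of 19 passing by edgeR or adjusted over the list alone. Shallow and deep medians were -0.60 and -0.15 for cholesterol synthesis, -0.31 and -0.16 for lysosome and autophagy, and -0.25 and 0.06 for glycolysis. All of them passed in the shallow (adjusted p = 1.63e-05, 0.00624 and 0.02) and none in the deep libraries (adjusted p = 0.823, 0.633 and 0.291). The glycolysis call ended when any of 22 single libraries was left out (adjusted p up to 0.099).

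Postsynaptic density and voltage-gated channel genes were higher in AD as lists in camera, while synaptic vesicle genes were not shown to differ as a list. Both list calls (adjusted p = 0.000612 each) ended with an estimated correlation (adjusted p = 0.589 and 0.69 with an estimated correlation). Of 34 postsynaptic density genes 3 rose and 0 fell, as adjusted over the list alone (median 0.24). The scaffolds were SHANK3 (2.39-fold, adjusted p = 0.0063, 25 of 27 AD libraries above the control median) and SHANK1 (3.21-fold, adjusted p = 0.0144). The other was NLGN2, an adhesion protein of inhibitory synapses (0.53 ± 0.17, adjusted p = 0.0434), which was at -0.38 on the FPKM scale, -0.05 from its median of all genes. Of 34 voltage-gated channel genes 1 rose, the T-type calcium channel CACNA1I (0.73 ± 0.24, adjusted p = 0.0481; -0.04 on the FPKM scale, 0.30 above its median), and 0 passed adjusted over the list alone (median 0.21). Within the shallow libraries both medians were negative, at -0.04 and -0.11 (adjusted p = 0.516 and 0.44), against 0.18 and 0.17 in the deep libraries (adjusted p = 0.0666 and 0.00722), where SHANK1 was at -0.44. The camera direction in the shallow libraries was up for the postsynaptic and down for the channel list. The channel list did not pass without control replicate 7 (median 0.12, adjusted p = 0.0508), and its median was 0.14 and 0.12 without control replicate 3 or 8. That of the postsynaptic list was 0.13 and 0.15 without control replicate 7 or 8. The NLGN2 call ended in 21 single omissions (adjusted p up to 0.0779) and that of CACNA1I in 28 (up to 0.0836).

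Of 40 synaptic vesicle and release genes 1 fell, SYPL1, a relative of synaptophysin (-0.88 ± 0.28, adjusted p = 0.0444), and 0 passed adjusted over the list alone (median -0.22, list adjusted p = 0.541). The SYPL1 call ended in 19 single omissions, and without control replicate 5 its change was -0.57 (adjusted p = 0.144). The list passed camera within each depth class with medians of opposite sign, -0.36 in the shallow (adjusted p = 2.61e-05) and 0.06 in the deep libraries (adjusted p = 0.0251), against adjusted p up to 0.943 under other alternatives. By permutation its score difference in the shallow libraries was -0.42 and did not pass (p = 0.131, adjusted p = 0.333). Among 22 glutamate receptor genes GRM3, a presynaptic and glial metabotropic receptor, fell (1.61-fold lower, adjusted p = 0.0159, 22 of 27 AD libraries below the control median) and 0 rose. Adjusted over the list alone 1 was lower (list median 0.19, adjusted p = 0.0607). The receptor list passed in the deep libraries, with a median of -0.09 but a camera direction of up (adjusted p = 0.0451), and not in the shallow libraries (-0.04, direction down, adjusted p = 0.597). Its adjusted p ran from 0.00315 to 0.697 over all alternatives. Of 22 GABA synthesis, transport and receptor genes 0 passed by edgeR or adjusted over the list alone, with a median of 0.00, a mean of -0.13 and a camera direction of up (adjusted p = 0.539). Of 36 axonal transport and microtubule genes 1 rose, the kinesin KIF1A (0.47 ± 0.14, adjusted p = 0.0388; -0.61 on the FPKM scale, 0.27 below its median). In the same list 4 fell, among them TUBA1A and the microtubule regulators STMN1 (2.19-fold lower, adjusted p = 0.00239) and STMN4 (2.32-fold lower, adjusted p = 0.0328). In all, 1 was higher and 8 lower adjusted over the list alone (list adjusted p = 0.188). The transport list passed in the shallow libraries (median -0.34, adjusted p = 0.0109) and not in the deep libraries (-0.27, direction up, adjusted p = 0.985), with adjusted p from 0.00381 to 0.985 over all alternatives. The KIF1A call ended in 10 single omissions (adjusted p up to 0.067). The STMN4 call ended without control replicate 4, 7 or 14 (-1.10, -1.14 and -1.003, adjusted p = 0.0655, 0.0644 and 0.0883).

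The panel of 13 genes set in advance for synapses, amyloid and glia had 0 members past the edgeR threshold and 5 at an unadjusted p under 0.05. DESeq2 called 1 of the 13, limma voom and the rank sum test 0, and limma on log2 FPKM 2, GAD1 and BACE1. Some alternatives called further members. Over all alternatives apart from single omissions the adjusted p of GRIN1 ran from 0.000175 to 0.989. That of GFAP ran from 0.00803 to 0.922 and that of SNAP25 from 0.0494 to 0.798. Log2 fold changes were -0.75 ± 0.33 for SNAP25, a vesicle fusion protein (adjusted p = 0.139), -0.79 ± 0.39 for SYP, the vesicle protein synaptophysin (adjusted p = 0.194), and -0.45 for the calcium sensor SYT1 (adjusted p = 0.432). The postsynaptic genes DLG4 (0.08, adjusted p = 0.832), CAMK2A (0.48, adjusted p = 0.219) and GRIN1 (0.29, adjusted p = 0.624) were not shown to differ either. GAD1, which makes GABA, had -1.03 ± 0.41 (adjusted p = 0.109). APP, the amyloid precursor, had -0.33 ± 0.23 (adjusted p = 0.358), the beta-secretase BACE1 -0.52 ± 0.22 (adjusted p = 0.124) and MAPT, which encodes tau, 0.37 ± 0.17 (adjusted p = 0.173). The astrocyte filament gene GFAP had 0.35 ± 0.42 and the mitochondrial MT-CO1 0.22 ± 0.53 (adjusted p = 0.624 and 0.828). Of the wider list of 21 amyloid precursor processing genes, the receptor LRP1 was 2.03-fold higher (adjusted p = 0.0142) and the paralog APLP1 1.91-fold lower (adjusted p = 0.0303). Of these genes 1 was higher and 2 lower adjusted over the list alone (median -0.28, list adjusted p = 0.541). Of 31 genes at AD risk loci 1 fell, the membrane-bending protein BIN1 (-0.94 ± 0.30, adjusted p = 0.0439), and 0 passed adjusted over the list alone (list adjusted p = 0.888). The APLP1 call ended without control replicate 5, 7 or 8 (-0.80, -0.57 and -0.89, adjusted p = 0.0552, 0.155 and 0.0501). That of BIN1 ended in 20 of the 41 single omissions (-0.48 without control replicate 7, adjusted p = 0.271).

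Complement and inflammatory signalling genes were higher as a list in camera (median 0.41, adjusted p = 0.0292, and adjusted p = 0.589 with an estimated correlation). Reactive astrocyte genes were as well (median 0.30, adjusted p = 0.0465, and adjusted p = 0.589 with an estimated correlation). Of 18 inflammatory genes TLR4, a receptor of innate immunity, rose (2.06-fold, adjusted p = 0.0378, 23 of 27 AD libraries above the control median) and 0 fell, with 1 higher adjusted over the list alone. The complement gene C4A, which shares reads with its near copy, was at 1.26 ± 0.48 without passing (adjusted p = 0.0934). Of 17 reactive astrocyte genes 0 passed by edgeR or adjusted over the list alone. The medians in the shallow and deep libraries were 0.29 and 0.63 for the inflammatory and 0.24 and 0.30 for the reactive astrocyte list. Both passed camera with the preset correlation in each class (adjusted p = 0.0348 and 3.84e-06, then 0.0298 and 0.0251). By permutation of the list scores neither passed in the shallow libraries (adjusted p = 0.406 and 0.333). Neither passed with groups permuted within depth classes (permutation, adjusted p = 0.159 and 0.182). The TLR4 call ended in 11 single omissions (adjusted p up to 0.0688). The inflammatory call ended without AD replicate 1, 2 or 4 or control replicate 2 or 9 (adjusted p up to 0.099; median 0.26 without AD replicate 4). The reactive astrocyte call ended in 21 single omissions (adjusted p up to 0.168; medians 0.20 and 0.19 without control replicate 4 or 9).

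Over the 33 lists, camera with a preset correlation of 0.01 called 13, 6 higher and 7 lower, and 0 with an estimated correlation (limma; lowest adjusted p 0.515). Fry asks whether the genes of a list move one way, without setting them against other genes, and called 4 lists. These were cholesterol synthesis (adjusted p = 0.00372), proteasome subunits (adjusted p = 0.00937), lysosome and autophagy (adjusted p = 0.00937) and nuclear encoded oxidative phosphorylation (adjusted p = 0.0124).

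**Figure D2:**
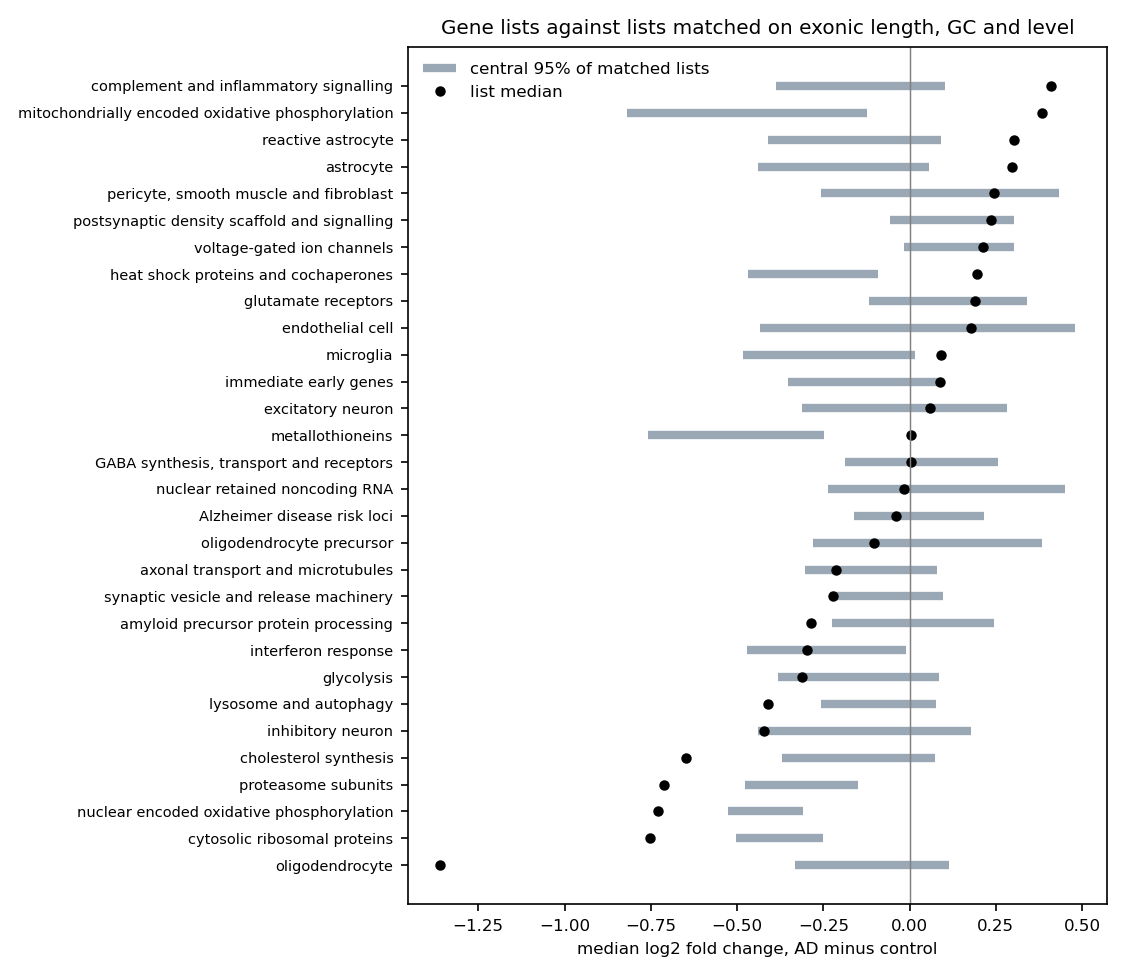
Median log2 fold change, AD minus control, of 30 gene lists (black points) and the central 95% of medians of 10000 lists of the same size matched on exonic length, GC content and level (grey bars). The oligodendrocyte median of -1.36 lay below its bar, which ran from -0.33 to 0.11, and the postsynaptic density median of 0.24 lay within its bar, from -0.06 to 0.30.

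Scored per library as the mean log2 CPM of their members, the same 4 lists differed between AD and control in two-sided permutation tests. Cholesterol synthesis averaged 3.95 ± 0.40 (SD, n = 27) in AD and 4.49 ± 0.40 (n = 14) in control, a difference of -0.54 (adjusted p = 0.0066, 22 of 27 AD libraries below the control median). Lysosome and autophagy genes differed by -0.33 (adjusted p = 0.012), proteasome subunits by -0.74 (adjusted p = 0.0198) and nuclear encoded oxidative phosphorylation genes by -0.79 (adjusted p = 0.0275). In these lists 22, 22 and 21 AD libraries lay below the control median. Oligodendrocyte markers differed by -0.84 (p = 0.0175, adjusted p = 0.106), with 24 of 27 AD libraries below the control median. Permuted within depth classes, the differences were -0.39 for cholesterol synthesis, -0.21 for lysosome and autophagy, -0.45 for the proteasome and -0.42 for the respiratory list (adjusted p = 0.143, 0.159, 0.172 and 0.182), so 0 of the 33 passed. In the shallow libraries alone cholesterol synthesis passed (-0.55, adjusted p = 0.0171).

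AD libraries varied less than control libraries in oligodendrocyte markers and more in heat shock genes. The mean absolute deviation of the oligodendrocyte score from the group median was 0.488 in AD and 1.22 in control (permutation p = 0.00131, adjusted p = 0.0335 over 33 lists). For heat shock proteins and cochaperones it was 0.513 in AD and 0.165 in control (permutation p = 0.00203, adjusted p = 0.0335). In the shallow libraries the differences in deviation were -0.65 and 0.43, and 0 of 33 lists passed (permutation, adjusted p = 0.315 and 0.293).

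**Figure D3:**
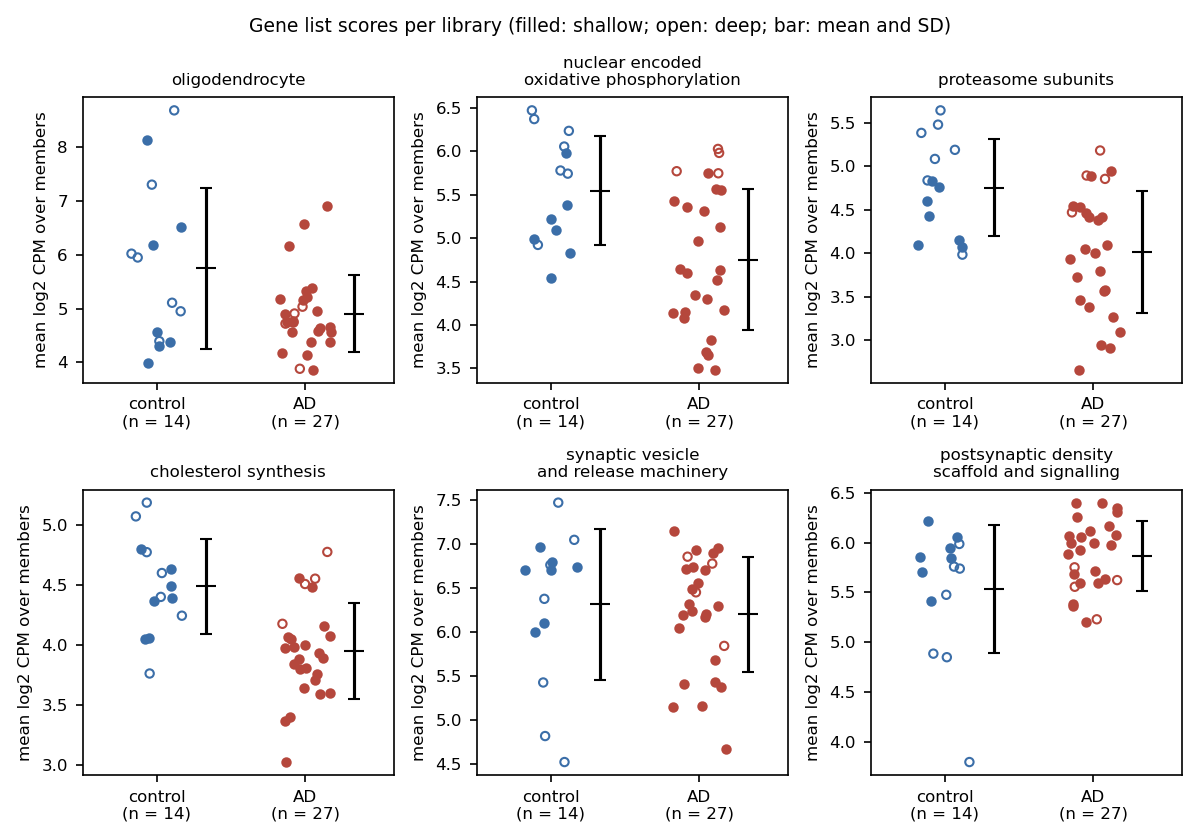
Mean log2 CPM over the members of 6 gene lists, with 1 point for each library (blue, control, n = 14; red, AD, n = 27; filled, shallow; open, deep) and bars for the mean and SD. Cholesterol synthesis lay at 3.95 in AD against 4.49 in control, and the oligodendrocyte score was spread more widely in control (mean absolute deviation 1.22) than in AD (0.488).

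Within AD, libraries with more mitochondrially encoded respiratory RNA held less synaptic vesicle RNA. The scores had Pearson r = -0.82 (n = 27, permutation p = 1e-05, the smallest 100000 resamples can give, adjusted p = 8e-05 over 8 correlations) and Spearman rho = -0.82 (adjusted p = 8e-05). Without the 2 libraries farthest from the median r was -0.81, and in the 23 shallow AD libraries it was -0.81 (adjusted p = 8e-05). The synaptic vesicle score also fell as the astrocyte score rose in AD (r = -0.54, adjusted p = 0.014; rho = -0.64, adjusted p = 0.00184; r = -0.61 without the 2 farthest libraries). This was r = -0.49 in the shallow AD libraries (permutation p = 0.018, adjusted p = 0.072). In control the vesicle score was related to the oligodendrocyte score by r = -0.66 (n = 14, adjusted p = 0.0289) but rho = -0.43 (adjusted p = 0.208), r being -0.57 without the 2 farthest libraries. Within classes this control relation was r = -0.31 in 7 shallow libraries (exact permutation p = 0.530) and r = -0.86 in 7 deep libraries (exact permutation p = 0.0107).

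The other 5 of the 8 correlations did not pass. In AD the vesicle score had r = -0.34 (rho = -0.09) with the oligodendrocyte score (adjusted p = 0.162 and 0.762) and r = 0.21 (rho = 0.24) with the nuclear encoded respiratory score (adjusted p = 0.336 and 0.295). In control, r was -0.41 with the astrocyte, -0.07 with the nuclear encoded respiratory and -0.32 with the mitochondrially encoded respiratory score (permutation adjusted p = 0.233, 0.801 and 0.336). The matching rho values were -0.45, -0.01 and -0.48 (adjusted p = 0.208, 0.977 and 0.208). Leaving out the 2 farthest libraries gave r = -0.21 and 0.06 for the AD pair of scores and -0.62, -0.15 and -0.69 for these control scores. The 4 deep AD libraries were too few for a correlation of their own, and whether AD and control differed in any correlation was not tested.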

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

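Alternatives with depth class, RN7SL1, the percent of mitochondrial counts, 5.8S RNA and the length and GC offset were chosen after the data were seen; the others were planned. At these depths and this spread between libraries 4.48% of genes changed 1.5-fold were recovered in simulated data, which did not separate depth from spread. Counts of genes higher and lower in AD, 357 and 519, became 123 and 119 with log2 library size as covariate, 133 and 90 with depth class as covariate, 231 and 319 with the RN7SL1 level, and 86 and 140 with the percent of mitochondrial counts. An offset for exonic length and GC gave 269 higher and 269 lower, and with depth class 19 and 11. Surrogate variables (5) gave 1083 and 1089, the Wald test of DESeq2 623 and 851 (adjusted p NA for 16168 genes), and limma voom 862 and 973. Limma on log2 FPKM called 0 higher and 890 lower (5584 at an unadjusted p under 0.05). The FPKM values were not rescaled between libraries, so a difference in scale is not set apart from changes of genes there. A log2 fold change of at least 1 left 128 and 153 by construction. The shallow class alone gave 5 and 0 and the deep class 1 and 0 by edgeR (1529 and 1643 at an unadjusted p under 0.05), with fewer libraries. The single gene of the deep class, AC243964.3, and the other 4 of the shallow class, ARHGAP31, ZHX3, KANK2 and HIF3A, were named after their values were seen. Other size factors, filters, thinning, the rank sum test and leaving out mitochondrial genes kept both counts within 1.5 times. The median log2 fold change of all genes was -0.06, against -0.34 on log2 FPKM and 0.26 for DESeq2 over 32069 genes. The rank sum test gives a difference in mean rank over the 41 libraries, with a median of -0.54, which is not a log2 fold change. Except where the setting itself removes genes or libraries, the cause was not tested.

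The replicate numbers did not pair AD with control libraries, but in AD they followed depth class, replicates 1 to 4 being the 4 deep libraries. The deep control libraries were replicates 3, 4, 7 to 10 and 14, so all deep libraries lie among numbers 1 to 14. What the numbers record is not given. Deviations of same-numbered libraries correlated between -0.61 and 0.63 (median -0.19), and 1 of 14 AD libraries correlated best with its own number. Libraries 1 to 14 gave 117 and 100 genes without the replicate block and 0 and 0 with it by edgeR (1656 at an unadjusted p under 0.05), and 14 lists either way.

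Leaving out single libraries gave 208 to 525 genes higher, 229 to 741 lower and 10 to 13 lists. Without control replicate 4, 7, 8, 9 or 14 the higher count was 222, 208, 228, 237 or 214, and without control replicate 7, 8, 9 or 14 the lower count was 229, 328, 330 or 328. The planned removal of libraries that correlate poorly with their group left out 0 libraries and gives no separate value.

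Of 13 lists, 0 passed with an estimated correlation and 4 by fry. List score differences went from 4 to 1 in the shallow class and 0 with groups permuted within depth classes, list score spreads from 2 to 0 and correlations from 3 to 1 in the shallow class. Reversed medians were 0.0582 for synaptic vesicle, 0.0555 for glycolysis and -0.33 for mitochondrially encoded oxidative phosphorylation genes in the deep class, -0.30 for the last with the percent of mitochondrial counts as covariate, and -0.11 for voltage-gated channels in the shallow class. Reversed genes included MTRNR2L8 (-0.49), SHANK1 (-0.44) and SOX9 (-0.24) in the deep class. On log2 FPKM, where the median of all genes was -0.34, KIF1A (-0.61) and NLGN2 (-0.38) were below that median. CIC (-0.23), ATN1 (-0.18), CACNA1I (-0.0373), DUSP1 (-0.0157), CUX2 (-0.0785), SLC7A5 (-0.0324) and CSF3R (-6.75e-05) were negative but above it. The pseudocount of 1 draws the change of a gene with low FPKM toward 0. A place above the median therefore does not show whether such a gene kept its direction. Of 67 named genes called, 26 still passed with depth class as a term, 44 with the length and GC offset, 8 with both, 67 with DESeq2, 1 in the shallow class and 0 in the deep class. Of named genes not called, 3, 7 and 1 passed with depth class, the offset and both.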

Other observations

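Heat shock genes, whose score varied more between AD than between control libraries (mean absolute deviation 0.513 against 0.165), included single genes that rose. The inducible chaperones HSPA1A (1.72 ± 0.52, medians 57.9 CPM in AD, n = 27, and 29.3 in control, n = 14) and HSPA1B (log2 fold change 1.68, adjusted p = 0.0499), which share reads as near copies, and the cochaperone BAG3 (1.30 ± 0.40, adjusted p = 0.0405, 26 of 27 AD libraries above the control median) rose. Of 27 heat shock genes 3 were higher and 0 lower, and 4 higher adjusted over the list alone (list median 0.19, adjusted p = 0.269). The list median lay above all lists matched on length, GC and level (central 95% from -0.47 to -0.09), and the list passed with the length and GC offset (median 0.31, adjusted p = 0.0291; 0.00538 to 0.767 over all alternatives). The HSPA1A call (adjusted p = 0.0364) ended in 9 single omissions, with adjusted p up to 0.0579, that of HSPA1B in 26 (up to 0.0858) and that of BAG3 in 14 (up to 0.0665). Of 18 immediate early genes FOSL2, an AP-1 subunit (2.20-fold), and DUSP1, a phosphatase of MAP kinases (2.20-fold; -0.02 on the FPKM scale, above its median of all genes), rose and 0 fell. Also adjusted over the list alone 2 were higher (list median 0.09, adjusted p = 0.0783), and the list passed in the deep (median 0.26, adjusted p = 0.0251) but not the shallow libraries (0.19, adjusted p = 0.139; 0.0123 to 0.588 over all alternatives). Metallothionein genes had 0 of 8 members past the edgeR threshold or adjusted over the list alone (median 0.00, mean 0.23, adjusted p = 0.188). With depth class as a term 1 rose, MT1H, whose counts are uncertain among near copies (log2 fold change 2.99, adjusted p = 0.0223, against 1.89 and 0.08 without the term; 0.0223 to 0.452 over all alternatives). They passed camera as a list within the shallow (median 0.92, adjusted p = 0.000265) and deep libraries (median 0.40, adjusted p = 0.0251). By permutation their score did not pass in the shallow libraries (adjusted p = 0.266) or with groups permuted within depth classes (adjusted p = 0.159). Over its alternatives that list's adjusted p ran from 9.96e-07 to 0.755. Interferon response genes had 0 of 23 past it either way (median -0.30, adjusted p = 0.143).

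Vessel and blood markers changed singly over all libraries, not as lists. In the list of pericytes, smooth muscle and fibroblasts, the mural receptors NOTCH3 (2.70-fold, adjusted p = 0.0128, 25 of 27 AD libraries above the control median) and PDGFRB (1.99-fold, adjusted p = 0.0222, 27 of 27) rose. In that list 0 of 12 fell, and 2 were higher also adjusted over the list alone. The list median was 0.25 (adjusted p = 0.282), at -0.07 in the shallow and 1.24 in the deep libraries (adjusted p = 0.97 and 3.84e-06, the extremes over its alternatives). Of 7 endothelial genes the amino acid transporter SLC7A5 rose (2.00-fold, adjusted p = 0.0105; -0.03 on the FPKM scale, above its median of all genes) and ITM2A fell (2.24-fold lower, adjusted p = 0.0291). There was 1 in each direction adjusted over the list alone (list median 0.18, adjusted p = 0.547). The leukocyte list had 2 genes tested, of which CSF3R, a granulocyte growth factor receptor, rose (3.13-fold, adjusted p = 0.00888; near 0 on the FPKM scale, above its median of all genes) over all genes and adjusted over the list alone (list median 0.98, adjusted p = 0.143). The leukocyte list passed in the deep (median 1.27, adjusted p = 0.0454) but not the shallow libraries (0.79, adjusted p = 0.188; 0.0454 to 0.589 over all alternatives). Red blood cell genes had 0 of 3 past either threshold (median -0.38, adjusted p = 0.143). FOXJ1, a regulator of motile cilia, rose 3.17-fold (adjusted p = 0.0127). It was 1 of 4 choroid plexus and ependyma genes, over all genes and adjusted over the list alone, in a list with a median of -0.31, a mean of 0.14 and a camera direction of up (adjusted p = 0.691). Nuclear retained noncoding RNA had 0 of 9 past either threshold (median -0.02, mean 0.10, direction up, adjusted p = 0.541).

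The tests within depth classes and the test of a lower share of oligodendrocyte material, in the paragraphs that follow, were chosen only after the results were seen; matched lists and splits of the libraries were set before their results were seen. Of 100 splits of the 41 libraries, 2 gave at least 357 genes higher and 1 gave at least 519 lower, the real split included (highest of the others 476 and 239). Chance alone was thus unlikely for both counts but is not excluded, and the splits did not hold the depth classes fixed. By edgeR 3122 genes had an unadjusted p under 0.05 in the real split, and up to 4090 in the others. The other split that reached the higher count put 0 of the 11 deep libraries among its 14. The real split put 7 there, and the other 4 splits with 7 or 8 gave 0 higher and 0 or 1 lower, so what that split follows stays open. Within depth classes 5 and 0 genes passed in the shallow and 1 and 0 in the deep libraries. For lists past the camera threshold chance could give the count, since 24 of 100 splits gave at least 13 (median of the others 9, highest 21).

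Oligodendrocyte markers were lower in AD synaptosomes as a list in camera, though not with an estimated correlation (adjusted p = 0.589 with an estimated correlation), and 13 of 19 fell. Against the length and GC trend as the cause, matched lists had a median of -0.10 while the list lay at -1.36, below all of them. The spread of the matched lists leaves out the correlation between markers, estimated at 0.64. Against depth class as the whole cause, the score difference was -0.79 with groups permuted within classes (permutation p = 0.0477). This is weak evidence, since the adjusted p over 33 lists was 0.182 and the shallow libraries alone gave -0.48 (p = 0.265). The value thus leans on the 11 deep libraries, control replicate 7 among them. In that class 4 of 4 AD but 3 of 7 control libraries were without 5.8S RNA. Permuting within classes does not hold this fixed, so a technical difference inside the deep class stays open. A smaller share of myelin fragments or oligodendrocyte RNA in the AD preparations may account for it, since 19 of 19 markers had negative fitted changes, but less myelin in AD tissue or less RNA per cell would do the same, and these cannot be told apart in a fraction with no measure of its purity. Control replicates 7 and 5 had the highest scores (8.69 and 8.14), and variable carry-over stays open beside disease itself.

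Nuclear genes of the respiratory chain, ribosomes and proteasome, with median exonic lengths of 2400, 3019 and 3909 bases, were lower in AD as lists in camera, with 18 of 74, 1 of 74 and 10 of 30 genes called and no list passing with an estimated correlation (adjusted p = 0.515, 0.589 and 0.515 with an estimated correlation). A length and GC trend may carry part of this. Matched lists had medians of -0.42, -0.38 and -0.32 while the lists lay at -0.73, -0.75 and -0.71, below all 10000 in each case. Whether the trend carries all of it stays open. Matched members were drawn independently, while the genes of these lists had estimated correlations of 0.57, 0.87 and 0.50. Exonic length also counts all annotated exons of a gene, not the transcript that was measured. Within depth classes the score differences were -0.42 (permutation p = 0.0579) for the respiratory, -0.31 (p = 0.322) for the ribosomal and -0.45 (p = 0.0286, adjusted p = 0.172) for the proteasome list. Depth class therefore could account for the ribosomal list, stays open for the respiratory list and is argued against, weakly, as the whole cause for the proteasome. Disease and RNA quality remain open for all of them; of signs of the latter per library, the nuclear retained noncoding RNA score differed by 0.20 (permutation p = 0.165; -0.07 within classes, p = 0.506) and the slope of expression on exonic length by 0.202 (p = 0.0322, adjusted p = 0.133; 0.0472 within classes, p = 0.513), while the slope on GC, per 10 percentage points, differed by 0.0225 (p = 0.836) but by 0.189 within classes (p = 0.048).

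Postsynaptic density and voltage-gated channel genes, with median exonic lengths of 8686 and 10043 bases, were higher in AD as lists in camera over all libraries, with 3 and 1 of 34 genes called. Neither passed with an estimated correlation (adjusted p = 0.589 and 0.69 with an estimated correlation), and both medians were negative in the shallow libraries (-0.04, camera direction up, and -0.11, direction down). Gene length and GC may account for the postsynaptic list, which lay at percentile 90.1 of matched lists (median 0.11) and did not pass with the length and GC offset (0.06, adjusted p = 0.081); for channels this stays open, since the list lay at percentile 79.2 (matched median 0.14) yet passed with the offset (0.10, adjusted p = 0.0291). Depth class may account for both, since the score differences within classes were 0.14 (permutation p = 0.387) and 0.0747 (p = 0.785). A change of single genes with disease stays open: SHANK3 was at 1.16 in the shallow and 0.67 in the deep libraries and passed in neither (adjusted p = 0.13 and 0.636), nor with the length and GC offset (0.92, adjusted p = 0.0641) or that offset with depth class (0.61, adjusted p = 0.399).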
